A study of Mus musculus with 11 samples.

How the data were processed

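Total RNA of 3 mouse cell lines (NMuMG mammary epithelium, E14 ES cells, NIH3T3 fibroblasts) was sequenced in 11 libraries, from parental cultures and cultures that carry a BRE reporter. Per the labels, RNA was extracted with RNeasy columns, libraries were made with the NEBNext Ultra RNA kit and reads came from a HiSeq instrument. The authors made base calls with bcl2fastq 1.8.4, aligned reads to the mm10 build with TopHat and quantified genes with Cufflinks, whose versions are not given. The deposited tables, 1 per library, hold FPKM (fragments per kilobase of transcript and per unit of mapped fragments) with the quantifier's interval for 23849 entries, and were used as deposited with no rescaling. Read counts were not used here.

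Entries that share a symbol were summed: 260 symbols stood on more than 1 entry (754 entries), which left 23355 symbols. A status of LOWDATA stood on 335 entries in at least 1 library. Rn45s, Tpm3 and Fn1 had failed in at least 1 library and were left out of every fit, so the fibroblast list was tested without Fn1. Of 1397 entries listed at 0 although their upper bound was above 0 in at least 1 library, 99.3% overlap another entry, against 16.0% of 11336 entries never at 0, so such a 0 is uncertain. Where a fold would be taken against a group at 0 the text says "listed at 0". Of 11978 symbols with 1 annotated gene on the same chromosome in a GENCODE mouse annotation, 99.8% overlap it.

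Relative depth was read from 493 entries at 0 in every library, as the ratio of their upper bounds to those of the parental ES library. It was 0.933 to 1.06 in library series 1, 1.13 to 1.28 in series 2 and 3.81 and 3.80 in series 3. Summed FPKM per library ranged from 429703 to 514980. Short RNA genes (Mir and Snor symbols) took 12.3% to 19.7% of it in series 1, 5.48% to 6.09% in series 2 and 3.80% and 4.86% in series 3. The deposited intervals were not used as errors, because 25.7% to 54.8% of the values above 5 FPKM lie outside their own interval. The relative depth rests on the same intervals, so it is uncertain too. Precision is therefore given by the spread between replicates, which covers counting error and culture differences together.

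Groups followed the labels. The 2 technical runs of 1 ES reporter culture were averaged and counted as 1 replicate. The tables of NIH3T3 replicates 2 and 3 could be matched to the line but not to a sample, although the labels give both remaining NIH3T3 samples as reporter cultures, so they entered the line comparisons and were left out of the reporter comparisons. The number runs in the table names were taken as 3 library series. In the reporter comparisons these series are also the replicate numbers of the labels.

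Changes were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with an intensity trend in the variance, two-sided, with Benjamini-Hochberg adjustment. The line comparisons used 10 replicates and genes of at least 1 FPKM in at least 3 of them. The reporter comparisons used 7 replicates (NMuMG parental 2, NMuMG reporter 2, ES parental 1, ES reporter 2) and genes of at least 1 FPKM in at least 2 of them. A gene was called, and is said to have risen or fallen, at an adjusted p under the 0.05 threshold with a fold of at least 2. Gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry as checks, and members were also counted adjusted over the list alone. Lists of fewer than 3 tested genes, the type I receptors, had no camera test. Receptor shares (percent of the summed FPKM of the 4 type I or 3 type II receptors) were compared with exact permutation tests. The procedure was tested on simulated data made from each gene's mean over all replicates and its residual SD. The noise was independent and normal, with no shift shared by a library or a series, so real error may be larger. Of 100 genes changed by 3 on the log2 scale, 95 to 98 were recovered in the line comparisons. It was 80 in the NMuMG and 70 in the ES reporter comparison. Of 100 changed by 1.5 it was 73 to 84 in the line comparisons, 56 and 30, with 3 to 9 false calls. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

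The comparisons, tests, the 27 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists cover BMP type I and type II receptors, other TGF-beta family receptors, co-receptors, SMADs, ligands, antagonists, BMP targets, pluripotency, epithelial, fibroblast, basal and luminal mammary, early differentiation, blood, adipocyte, skeletal muscle and endothelial genes, Wnt receptors, the Notch pathway, FGF receptors, Eph and ephrin genes, the hedgehog pathway, proliferation, the p53 and INK4 pathway, cholesterol synthesis and interferon-stimulated genes. Some genes are in more than 1 list, such as Krt8 and Krt18. Named genes are the BMP receptors, the 5 called genes with the largest fold in each direction whose replicates do not overlap (leaving out unnamed and short RNA genes and a gene not printed), and up to 4 called members of each list. In the reporter comparisons they are the 5 called genes with the largest fold in each direction, or the 3 with the smallest p where none was called. Mki67, Plk1 and Isg15 were chosen after their values were seen.

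Alternatives were another pseudocount (0.1 or 0.5), no filter, a filter at 5 FPKM, TPM, median-of-ratios and quantile scaling, no fold minimum, a single technical run, symbols on 1 entry only, each replicate left out, only the lines compared, the series or the replicate number as a term, parental cultures only, array weights and the reporter as a covariate. Chosen after seeing the data were the fits within a library series, those without uncertain zeros, without LOWDATA entries or without Mir and Snor genes, the fit without both interferon-high libraries, and the list counts by series.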

Results

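Transcripts from total RNA were sequenced in 3 mouse cell lines that are used to study how cells read combinations of BMP ligands. NMuMG is an epithelial line from normal mammary gland, the embryonic stem (ES) cells are the E14 line grown with LIF and serum, and NIH3T3 is a fibroblast line from embryo. Some cultures were the parental line and others carried a BRE reporter, a fluorescent reporter gene placed behind a BMP response element. The 11 libraries gave 4 NMuMG replicates (parental replicates 1 and 3, reporter replicates 2 and 4), 3 ES replicates (parental replicate 1, reporter replicates 2 and 4, with 2 technical runs of 1 reporter culture averaged into replicate 2) and 3 NIH3T3 replicates. Replicate 1 of NIH3T3 was parental. The labels give the other 2 NIH3T3 samples as reporter cultures, but their tables, whose names lack the reporter mark, could not be matched to them one by one and entered no reporter comparison. The libraries fell into 3 library series: ES replicates 1 and 2 with NMuMG replicates 1 and 2, then ES replicate 4 with NMuMG replicates 3 and 4 and NIH3T3 replicate 1, then NIH3T3 replicates 2 and 3. The tables give no read counts, so absolute depth is unknown. Relative to the parental ES library, depth as read from the deposited intervals, which many values lie outside, was 0.933 to 1.06 in library series 1, 1.13 to 1.28 in series 2, and 3.81 and 3.80 in NIH3T3 replicates 2 and 3. Between 10353 and 11049 table entries reached 1 FPKM in a library. All values are FPKM means ± SD over the replicates of a line (n = 4 for NMuMG, n = 3 for ES and for NIH3T3), and changes are limma log2 changes with their SE.

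The first comparison asks how the BMP signalling components and the cell identity of ES cells differ from those of NMuMG cells. Acvr1, a type I receptor (chromosome 2, 58446438 to 58566828, mm10), stood at 12.4 ± 2.05 FPKM in NMuMG and 1.74 ± 0.298 in ES cells, a log2 change of -2.29 (SE 0.171, adjusted p = 1.33e-06). Acvr2b, a type II receptor that also binds activins (chromosome 9, 119402501 to 119433506), went the other way, from 2.09 ± 0.282 to 10.99 ± 2.44 FPKM, a log2 change of 1.94 (SE 0.188, adjusted p = 8.84e-06). Bmpr2, the type II receptor most specific for BMPs (chromosome 1, 59764637 to 59870859), fell from 6.77 ± 0.902 to 2.05 ± 0.509 FPKM, a log2 change of -1.36 (SE 0.178, adjusted p = 7.38e-05). Bmpr1a (chromosome 14, 34411068 to 34502546) had the highest mean of the type I receptors in every line, although in NMuMG replicate 4 Acvr1 made up 52.4% of the type I total and Bmpr1a 47.6%. It was not called here, at 16.2 ± 2.06 and 11.9 ± 1.59 FPKM, log2 change -0.41. Acvr2a (chromosome 2, 48814109 to 48903264) was not called either, at 4.92 ± 0.335 and 3.35 ± 0.702 FPKM, log2 change -0.46. Bmpr1b and Acvrl1 were too low to test, with ES means of 0.133 and 0.503 FPKM and NMuMG means of 0.0065 and 0.0216. Within library series 1 the log2 changes of Acvr1, Acvr2b and Bmpr2 were -2.23, 2.15 and -1.11, all called. Within series 2, where the lone ES sample is assumed to vary like the other groups, they were -2.35, 1.60 and -1.72 and none passed (adjusted p = 0.0655, 0.0525 and 0.0572). Fitted with the series as a term they were -2.28, 1.93 and -1.35. In parental cultures only, with 1 ES replicate, Bmpr2 was at -1.27. The spread of that fit comes from NMuMG replicates 1 and 3 alone, so its tests say little. Quantile normalization of the values left Bmpr2 just under a 2-fold change, at -0.99.

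**Figure D1:**
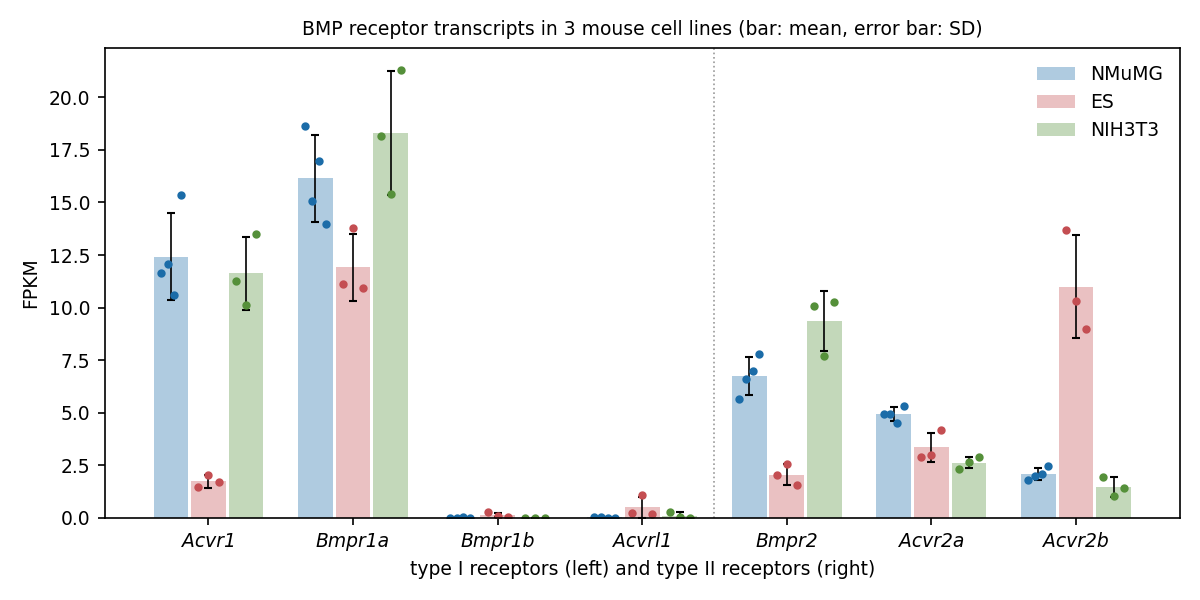
FPKM of the 7 BMP type I and type II receptors in each replicate of NMuMG (n = 4), ES (n = 3) and NIH3T3 (n = 3), with bars for the mean, error bars for the SD and points for replicates. Acvr1 averaged 1.74 FPKM in ES cells against 12.4 in NMuMG and 11.6 in NIH3T3, and Acvr2b averaged 10.99 in ES cells against 2.09 and 1.46.

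Downstream of the receptors, ES cells held less of several signal transducers and targets than NMuMG. Of 10 SMAD and SMURF genes tested, 4 fell and 1 rose. Smad3, which carries TGF-beta and activin signals, fell by 3.53 on the log2 scale (SE 0.246, 33.8 ± 5.49 to 2.11 ± 1.06 FPKM), Smad1, a BMP transducer, fell by 1.54 (SE 0.231), and the inhibitory Smad6 fell by 2.75 (SE 0.292). The inhibitory Smad7 rose by 1.23 (SE 0.288), but it was at 0.92 without ES replicate 4 and at 0.91 within series 1, neither of them called. In the fits with 1 ES replicate Smad7 was at 0.50 in parental cultures only and at 1.86 within series 2. Of 11 genes commonly induced by BMP, 7 fell, among them Id2 (log2 change -4.65, SE 0.306, 397 ± 46.7 to 15.7 ± 7.24 FPKM), an inhibitor of helix-loop-helix factors, and the bone regulator Runx2 (-3.20, SE 0.141), and 2 rose. Of 15 BMP, GDF and TGF-beta ligand genes, 5 rose, led by Gdf3 (4.94, SE 0.19), Nodal (4.71, SE 0.226) and Lefty2 (4.68, SE 0.388), which act in the early embryo, and 7 fell, led by the stress-induced Gdf15 (-5.13, SE 0.271). Of 10 secreted antagonists, 2 rose, Fstl1 (3.09, SE 0.349) and Htra1 (1.71, SE 0.474), and 5 fell, including Nbl1 (-4.42, SE 0.433) and Twsg1 (-2.49, SE 0.251). Within series 2, with its lone ES sample, 0 antagonists were called (limma), at a median log2 change of -0.65 as over all replicates. The Nodal co-receptor Tdgf1 rose by 8.02 (SE 0.275), and Neo1 was the 1 co-receptor of 7 tested that fell (-1.93, SE 0.181). Eng was the second that rose, at 7.86 ± 0.286 FPKM in ES cells and listed at 0 in NMuMG, where its table entry shares its locus with another. Of 4 other TGF-beta family receptors, Tgfbr2 (-4.63, SE 0.231) and Tgfbr1 (-1.72, SE 0.172) fell and Amhr2 (1.61, SE 0.142) rose. None of these BMP lists moved as a whole relative to other genes (limma camera, adjusted p = 0.31 for the SMADs, 0.458 for the targets, 0.749 for the antagonists, 0.506 for the co-receptors, 0.795 for the other receptors and 0.916 for the ligands and for the type II receptors). The type II receptors had a median log2 change of -0.46 and a mean of 0.04, since Acvr2b and Bmpr2 moved apart. Adjusted over the list alone, each of these lists had as many called members as over all genes.

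ES cells carried the pluripotency programme that NMuMG cells lack. Of 25 pluripotency genes 23 rose and none fell (limma; 23 adjusted over the list alone). Dppa5a, an RNA-binding protein of ES cells, rose from 0.929 ± 0.786 to 2049 ± 251 FPKM (log2 change 10.13, SE 0.276, adjusted p = 1.96e-09). Pou5f1, which encodes OCT4, rose from 0.807 ± 0.403 to 1086 ± 53.8 FPKM (9.26, SE 0.183), and Zfp42 and Utf1 rose by 8.49 and 8.22. Trh, a hormone precursor, rose by 8.17 (SE 0.285). In the other direction the largest changes were in the membrane proteins Tm4sf4 (-9.74, SE 0.208, 1118 ± 125 to 0.309 ± 0.155 FPKM), Tmem176b (-9.05, SE 0.278) and Tspan8 (-8.41, SE 0.176) and in the cornified envelope gene Sprr1a (-9.61, SE 0.365). Igfbp7 stood at 653 ± 56.8 FPKM in NMuMG and was listed at 0 in ES cells. The pluripotency list rose as a whole (camera adjusted p = 2.82e-15, and adjusted p = 0.0268 with an estimated correlation). With the library series as a term 23 of its genes rose, as within series 1, and within series 2 it was 22.

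The epithelial genes split between both lines. Of 25 tested, 13 fell in ES cells, led by the keratins Krt18 (log2 change -8.04, SE 0.297, 2502 ± 442 to 9.14 ± 4.20 FPKM), Krt7 (-7.91), Krt8 (-7.50) and Krt19 (-7.28), and 10 rose. All 3 luminal mammary genes tested, Krt8, Krt18 and the pioneer factor Foxa1 (-3.37, SE 0.234), fell (camera adjusted p = 0.0258, and adjusted p = 0.582 with an estimated correlation). Of 28 fibroblast genes 7 fell, such as Vim (-3.26, SE 0.298), Cdh2 (-3.84) and S100a4 (-4.73), 2 rose and 19 were not called, with a median log2 change of 0.00 and a mean of -0.52. The 3 endothelial genes tested, Pecam1 (3.24, SE 0.145), Esam (1.40) and Tek (1.36), rose (camera adjusted p = 0.0258, and adjusted p = 0.592 with an estimated correlation). Of 20 proliferation genes 16 rose and 2 fell (19 adjusted over the list alone), with Ccne1 at 4.69 (SE 0.614), Mcm5 at 3.71 (SE 0.841) and Ccnb1 at 3.61 (SE 0.704) and Ccnd1 at -3.19 (SE 0.518). Camera gave adjusted p = 0.0252 for that list, and adjusted p = 0.807 with an estimated correlation. Within series 1 16 of its genes rose, within series 2 0 rose (limma), and with the series as a term 14 rose, while its median log2 change stayed about as large, at 2.28, 2.34 and 2.34 against 2.39 over all replicates. NMuMG replicate 4 stood apart in these genes, with Mki67 at 0.96 FPKM against 10.3, 16.8 and 31.7 in replicates 1, 2 and 3. The mean log2 level of the list was 6.13 in ES replicate 4, 5.62 in NMuMG replicate 3 and 2.66 in NMuMG replicate 4. The median within series 2 thus rests mostly on NMuMG replicate 4.

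Over all genes, 5651 of 12350 tested differed at least 2-fold between ES and NMuMG cells (limma, adjusted p under the 0.05 threshold), 2392 higher and 3259 lower in ES cells. With quantile normalization the higher genes outnumbered the lower, 2876 against 2732. Within series 1 the count was 5865, within series 2 it was 2135, and with the series as a term it was 5657, of which 5538 were shared. Among the 5651, 196 involve an entry listed at 0 although its upper bound is above 0.

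The second comparison asks the same of NIH3T3 fibroblasts against NMuMG. No BMP receptor was called. Acvr1 stood at 11.6 ± 1.73 FPKM in NIH3T3 (log2 change -0.09, adjusted p = 0.738), Bmpr1a at 18.3 ± 2.94 (0.17, adjusted p = 0.452), Bmpr2 at 9.35 ± 1.43 (0.41, adjusted p = 0.0907) and Acvr2b at 1.46 ± 0.463 (-0.34, adjusted p = 0.178). The sign for Acvr1 turned with quantile normalization (0.013) and without NMuMG replicate 4 (0.014) or NIH3T3 replicate 2 (0.002). Acvr2a, at 2.63 ± 0.270 FPKM, had an adjusted p of 0.00377 with a change below 2-fold (-0.71, SE 0.152). Within series 2 the log2 changes were -0.17 for Acvr1, 0.23 for Bmpr1a, 0.40 for Bmpr2, -0.82 for Acvr2a and -0.16 for Acvr2b. That fit holds 1 NIH3T3 library, replicate 1, which is assumed to vary like NMuMG, so the lack of a call there says little. A series term rests on the same NIH3T3 library, since series 3 holds NIH3T3 alone and its libraries are absorbed by the term. The genes around the receptors did differ. Of 7 co-receptors 3 rose and none fell: Tgfbr3, or betaglycan (log2 change 4.65, SE 0.204, 0.148 ± 0.148 to 28.5 ± 8.49 FPKM), Rgma (4.04, SE 0.153) and Rgmb (2.14, SE 0.226), which bind BMP ligands (camera adjusted p = 0.04, and adjusted p = 0.145 with an estimated correlation). Of 10 secreted antagonists 5 rose and none fell, among them Fstl1 (7.21, SE 0.349, 0.411 ± 0.458 to 220 ± 124 FPKM), Bmper (2.63, SE 0.254) and Fstl3 (1.33, SE 0.298); camera gave adjusted p = 0.0136, and adjusted p = 0.133 with an estimated correlation. Fitting the series as a term left 4 antagonists and 4 co-receptors higher, and within series 2 it was 2 and 3, with list medians of 1.29 and 1.08 for the antagonists against 0.82 over all replicates and 1.62 and 1.76 for the co-receptors against 0.90.

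The SMADs were close in both lines, with 1 of 10 called, Smad9 (log2 change 1.33, SE 0.166). Of 11 BMP targets 4 rose, including the blood and vessel regulator Gata2 (2.99, SE 0.137) and Id4 (2.90, SE 0.401), and 2 fell, Id2 (-3.26, SE 0.306, 397 ± 46.7 to 42.4 ± 15.3 FPKM) and Msx1, which averaged 4.35 ± 0.957 FPKM in NMuMG and was listed at 0 in NIH3T3. Of 15 ligand genes 3 rose, such as Tgfb3 (2.55, SE 0.445), and 5 fell, such as Gdf15 (-6.52, SE 0.271) and Bmp4 (-3.08, SE 0.482). None of the 4 other TGF-beta family receptors was called. Camera called none of these lists (adjusted p = 0.936, 0.551, 0.873 and 0.405 in that order). Adjusted over the list alone, the BMP lists had as many called members as over all genes.

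Fibroblast genes were higher and epithelial genes lower in NIH3T3 than in NMuMG cells. Of 28 fibroblast genes 27 rose and none fell (27 adjusted over the list alone), with the collagens Col1a2 (log2 change 9.95, SE 0.283, 0.173 ± 0.206 to 1217 ± 530 FPKM) and Col1a1 (9.45, SE 0.337), the collagen crosslinking enzyme Lox (8.95, SE 0.399) and the surface protein Thy1 (8.11, SE 0.298). The proteoglycan Bgn (9.95, SE 0.234) and Serpinf1 (8.96, SE 0.227) were among the 5 largest increases. Of 25 epithelial genes 15 fell and none rose: Krt18 fell from 2502 ± 442 to 0.128 ± 0.223 FPKM (-11.12, SE 0.297, adjusted p = 2.04e-09), as did Krt8 (-10.46), Krt19 (-9.72) and the protease inhibitor Spint2 (-8.88). All 3 luminal genes fell, and Clu (-9.75, SE 0.747), Tm4sf4 (-9.80) and Sprr1a (-10.08) were the largest falls outside the keratins. Camera gave adjusted p = 6.31e-19 for the fibroblast, 2.21e-08 for the epithelial and 0.000739 for the luminal list, and adjusted p = 0.118 with an estimated correlation for each. With the series as a term 22 fibroblast genes rose and 15 epithelial genes fell, and within series 2 it was 21 and 11.

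Camera called several further lists with the preset correlation and not with an estimated one, and fry called the hedgehog, early differentiation and p53 lists among them (adjusted p = 7.28e-06, 3.6e-06 and 2.69e-06) but not the proliferation and cholesterol lists (0.216 and 0.172). Of 9 hedgehog genes 3 rose, Gas1 (log2 change 7.49, SE 0.342), Gli3 (2.79, SE 0.205) and Gli2 (2.26, SE 0.272), and none fell (camera adjusted p = 0.00908, and adjusted p = 0.135 with an estimated correlation). Of 9 early differentiation genes 6 fell, including the endoderm factor Foxa2 (-5.28, SE 0.214) and the neural filament gene Nes (-4.59, SE 0.472), and 1 rose (0.00484, and adjusted p = 0.212 with an estimated correlation). Of 9 p53 and INK4 pathway genes 5 fell, including Cdkn2b (-6.03, SE 0.347) and Cdkn1a (-2.46, SE 0.349), and 1 rose (0.04, and adjusted p = 0.145 with an estimated correlation). Of 20 proliferation genes 2 rose and Ccnd1 (-3.08, SE 0.518) fell (0.04, and adjusted p = 0.682 with an estimated correlation), and of 14 cholesterol synthesis genes 5 rose, such as Idi1 (1.55, SE 0.352), and none fell (0.0458, and adjusted p = 0.682 with an estimated correlation). In the fit with a series term 0 proliferation genes and 3 cholesterol genes rose, and within series 2 0 cholesterol genes rose (limma). The median log2 change was 1.36 with the term against 1.15 for the proliferation genes, and 0.81 with the term and 0.68 within series 2 against 0.94 for the cholesterol genes. The proliferation means of the lines overlapped, at 4.15, 4.55, 5.62 and 2.66 (log2) in NMuMG replicates 1 to 4 and 5.26, 5.66 and 4.63 in NIH3T3. In series 2 NIH3T3 replicate 1 lay below NMuMG replicate 3 and above NMuMG replicate 4. The cholesterol means of NMuMG followed the series, at 4.14 and 4.39 (log2) in replicates 1 and 2 and 5.72 and 5.58 in replicates 3 and 4. Over all genes 3085 of 12350 differed, 1307 higher and 1778 lower in NIH3T3. The count was 907 within series 2, where more were higher (535) than lower (372), and 941 in parental cultures only (565 and 376), and both fits rest on the same NIH3T3 library, replicate 1. It was 2509 with the series as a term, 2272 of them shared, in a fit that rests on that NIH3T3 library too.

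The third comparison sets ES cells against NIH3T3. Acvr1 was lower in ES cells (log2 change -2.20, SE 0.182, adjusted p = 3.34e-06), as was Bmpr2 (-1.77, SE 0.19, adjusted p = 2.06e-05), and Acvr2b was higher (2.28, SE 0.201, adjusted p = 5.14e-06). Bmpr1a (-0.57, SE 0.173) and Acvr2a (0.25, SE 0.162) were not called. With the series as a term the log2 changes of Acvr1, Bmpr2 and Acvr2b were -2.13, -1.87 and 1.98, all called. Within series 2, with 1 replicate per line, they were -2.18, -2.12 and 1.76. The spread there comes from NMuMG replicates 3 and 4 alone, so that test (limma adjusted p = 0.0923, 0.0604 and 0.0611) says little. In parental cultures only, again with 1 replicate each of ES cells and NIH3T3, Bmpr2 was at -1.88. The spread of that fit comes from NMuMG replicates 1 and 3 alone. Of 10 antagonists 8 fell in ES cells and none rose (9 adjusted over the list alone), including Fstl1 (-4.12, SE 0.374), Nbl1 (-3.62, SE 0.463) and Fstl3 (-3.03, SE 0.318). Camera gave adjusted p = 0.00537 for them, and adjusted p = 0.0856 with an estimated correlation. In the fit with a series term 7 antagonists fell, and within series 2 it was 2, at medians of -2.21 and -2.36 against -2.60. Of 11 BMP targets 7 fell, such as Atoh8 (-4.08, SE 0.43), Runx2 (-3.54, SE 0.15) and Id3 (-2.95, SE 0.445), and Smad7 rose (1.98, SE 0.307, but 0.88 in parental cultures only). Of 10 SMAD genes 5 fell, such as Smad3 (-2.59, SE 0.263), and 1 rose. Of 15 ligands 7 rose, such as Gdf3 (4.94), and 7 fell, such as Tgfb3 (-4.69). Of 7 co-receptors 2 rose, led by Tdgf1 (8.22), and 4 fell, led by Tgfbr3 (-4.59), and of the 4 other receptors Tgfbr2 fell (-4.09) and Amhr2 rose (1.56), with a list median of 0.05 and a mean of -0.61. Apart from the antagonists these lists were not called by camera (adjusted p = 0.0734 for the targets, 0.136 for the SMADs, 0.703 for the ligands, 0.48 for the co-receptors, 0.867 for the other receptors and 0.793 for the type II receptors), and adjusted over the list alone each had as many called members as over all genes.

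ES cells and NIH3T3 also differed in cell identity genes. All 25 pluripotency genes rose (25 adjusted over the list alone), with Dppa5a at 10.60 (SE 0.295), Pou5f1 at 9.93 (SE 0.196), Zfp42 at 8.82 and Utf1 at 8.40. All 28 fibroblast genes fell, led by the calcium-binding S100a4 (-11.63, SE 0.551, 4639 FPKM in NIH3T3 to 0.603 ± 1.04 in ES cells), Col1a2 (-9.93), Col1a1 (-9.56) and Lox (-8.94). Bgn, outside that list, fell by 10.04. Of 25 epithelial genes 23 rose and none fell, including Spint2 (7.22, SE 0.232), the adhesion genes Cdh1 (6.26, SE 0.147) and Epcam (6.14, SE 0.303) and the claudin Cldn6 (4.62, SE 0.304). Camera gave adjusted p = 4.55e-15, 2.62e-13 and 1.33e-10 for these lists, and adjusted p = 0.0279, 0.0856 and 0.0856 with an estimated correlation. The 3 endothelial genes rose as well (0.0268, and adjusted p = 0.38 with an estimated correlation). With the series as a term 23 pluripotency genes rose, 26 fibroblast genes fell and 22 epithelial genes rose, and within series 2 it was 23, 24 and 16. Over all genes 5315 of 12350 differed, 2478 higher and 2837 lower in ES cells, and with quantile normalization 2677 higher and 2597 lower. The count was 1735 within series 2 and 4774 with the series as a term, 4278 of them shared, both with replicate 1 alone for NIH3T3. Across the 3 line comparisons, the pluripotency list in ES cells against each other line was the one camera call that held with an estimated correlation.

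**Figure D2:**
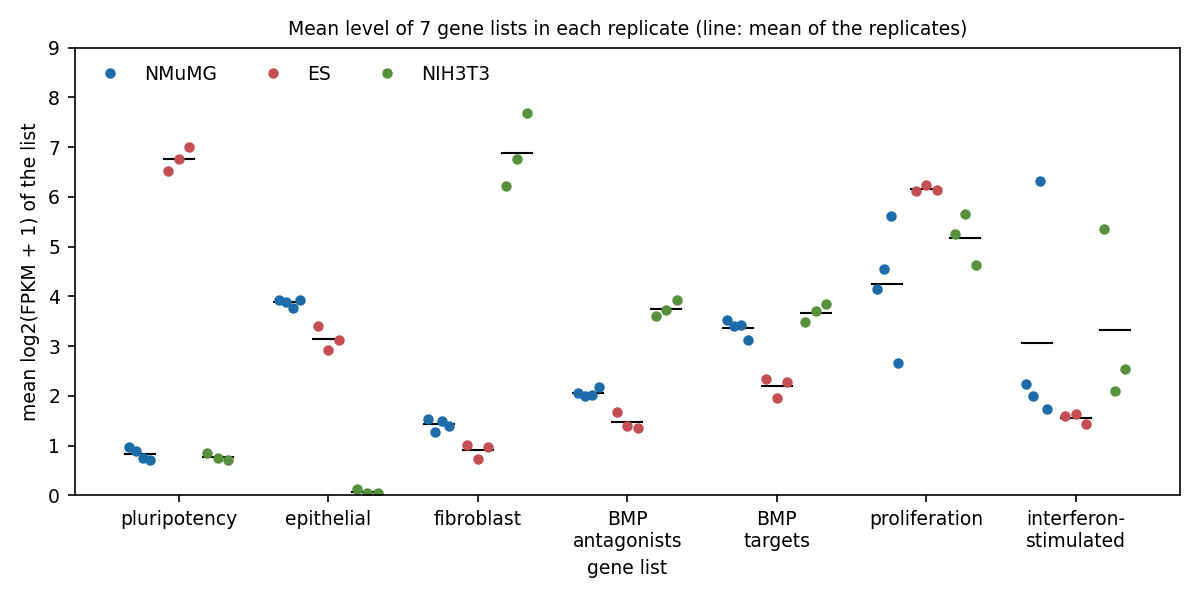
Mean log2(FPKM + 1) of 7 gene lists in each replicate (points) of NMuMG, ES and NIH3T3, with a line at the mean of the replicates. The interferon-stimulated genes reached 6.33 in NMuMG replicate 3 and 5.35 in NIH3T3 replicate 1, and the proliferation genes were lowest, at 2.66, in NMuMG replicate 4.

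Other signalling receptors were shared out among the lines gene by gene, and camera called none of the lists that follow in the comparisons given here. Fgfr1 was almost absent from NMuMG (0.0743 ± 0.0646 FPKM) and stood at 14.35 ± 4.11 in ES cells and 75.0 ± 36.4 in NIH3T3, while Fgfr3 stood at 25.2 ± 19.9 in NMuMG, 0.456 ± 0.167 in ES cells and 0.00441 ± 0.0055 in NIH3T3. The FGF receptor list had 1 member higher and 2 lower of 4 in ES cells against NMuMG, 2 higher and 1 lower in NIH3T3 against NMuMG (4 adjusted over the list alone), and 0 higher and 3 lower in ES cells against NIH3T3. Of 15 Wnt receptors, 5 rose and 5 fell in ES cells against NMuMG, with Fzd1 lower (-4.33, SE 0.195), and 4 rose and 1 fell in NIH3T3 against NMuMG, with Ror2 higher (3.77, SE 0.268). In ES cells against NIH3T3 4 Wnt receptors rose and 9 fell. Of 10 Notch pathway genes, 3 rose and 4 fell in ES cells against NMuMG, with the ligand Jag1 lower (-3.34, SE 0.284), at a median of 0.07, a mean of -0.20 and an upward test. That median changed sign between the series, at 0.39 within series 1 and -0.78 within series 2, with its lone ES sample. In NIH3T3 5 Notch genes fell against NMuMG, Jag1 by 3.89, and none rose. With the series as a term 3 fell and 1 rose, at a list median of -0.68, and within series 2 the median was -0.79. In ES cells against NIH3T3 5 Notch genes rose, with Jag2 higher (3.09, SE 0.474), and 1 fell. Of 15 Eph and ephrin genes, 4 rose and 9 fell in ES cells against NMuMG, with Efna1 (-4.09, SE 0.261) and Efnb1 (-3.84, SE 0.177) lower. In NIH3T3 3 rose, with Ephb2 higher (3.22, SE 0.144), and 7 fell against NMuMG (2 and 3 with the series as a term and 1 and 2 within series 2, at a list median of -0.77 and -0.75 against -0.88), and in ES cells against NIH3T3 3 rose and 7 fell. Of 9 hedgehog genes, 4 rose, such as Gli2 (3.18, SE 0.272), and 1 fell in ES cells against NMuMG, and 3 rose and 4 fell against NIH3T3, with Gas1 lower (-7.47, SE 0.366). Against NMuMG the hedgehog median was 1.49 within series 1 (8 genes tested) and -0.08 within series 2 (9 genes tested, lone ES sample).

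The remaining lists cover cell types and states. Of 9 early differentiation genes, 6 fell in ES cells against NMuMG, with Foxa2 at -4.60 (SE 0.214), and 1 rose, and against NIH3T3 1 rose, Pax6 (1.73, SE 0.226). Of 5 basal mammary genes, 2 fell, with Mylk at -3.00 (SE 0.466), and the basal keratin Krt17 rose (3.46, SE 0.469) in ES cells against NMuMG, at a mean of 14.001 ± 13.4 FPKM. In NIH3T3 the smooth muscle actin Acta2 rose (7.39, SE 0.766) and 1 basal gene fell (3 adjusted over the list alone), and 2 rose and 2 fell in ES cells against NIH3T3. Of 3 luminal genes, Krt18 (3.08) and Krt8 (2.96) rose in ES cells against NIH3T3. Of 3 adipocyte genes tested, Cebpa (-3.75, SE 0.187) and Pparg (-3.07, SE 0.146) fell in ES cells against NMuMG, and both fell while Lpl rose (3.56, SE 0.271) in NIH3T3. In ES cells against NIH3T3 Lpl fell (-2.63, SE 0.289). Of 3 skeletal muscle genes, Mylpf (4.29, SE 0.229) and Des (1.91, SE 0.281) rose in ES cells against NMuMG, both rose against NIH3T3, and 0 differed between NIH3T3 and NMuMG (limma). The 3 endothelial genes were not called between NIH3T3 and NMuMG, with a median of 0.02 and a mean of -0.01. Of 3 blood cell genes tested, Coro1a rose (2.66, SE 0.158) and Cd14 fell (-7.59, SE 0.367) in ES cells against NMuMG, at a median of 0.96, a mean of -1.32 and an upward test, Cd14 fell by 5.06 in NIH3T3 against NMuMG, and 2 rose and Cd14 fell in ES cells against NIH3T3. Of 9 p53 and INK4 pathway genes, 5 fell, with Cdkn2b at -5.30 (SE 0.347), and 2 rose in ES cells against NMuMG, and 4 rose and 2 fell against NIH3T3, with Cdkn2c at -4.86 (SE 0.365). Of 14 cholesterol genes, 4 fell, with Cyp51 at -3.59 (SE 0.491), and none rose in ES cells against NMuMG (3 adjusted over the list alone), at a median of 0.01 and a mean of -0.28, and 5 fell against NIH3T3. Of 10 interferon-stimulated genes, none was called in ES cells against NMuMG, 1 rose in NIH3T3 against NMuMG (0 adjusted over the list alone) and 2 fell in ES cells against NIH3T3 (1 adjusted over the list alone). Of 20 proliferation genes 4 rose and 1 fell in ES cells against NIH3T3 (3 adjusted over the list alone, and 0 rose with the series as a term by limma, at a median of 1.14 against 1.18). Of 25 pluripotency genes 2 rose, Klf2 (2.54, SE 0.189) and Tbx3 (2.29, SE 0.488), and 2 fell in NIH3T3 against NMuMG (3 adjusted over the list alone), at a median of -0.03, a mean of -0.06 and an upward test, and with the series as a term none fell. None of the lists of this paragraph was called by camera in the comparison given. Over all 27 lists, called members, counted once per list, numbered 186, 126 and 196 in the comparisons of ES with NMuMG, NIH3T3 with NMuMG and ES with NIH3T3, 185, 106 and 173 with the series as a term, and 113, 69 and 116 within series 2.

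The mix of BMP receptors was compared as shares of the summed FPKM. Among type I receptors, Bmpr1a made up 56.5% ± 6.56 in NMuMG, 83.6% ± 2.28 in ES cells and 60.9% ± 0.52 in NIH3T3, and Acvr1 made up 43.4% ± 6.59, 12.2% ± 1.06 and 38.8% ± 0.83. Among type II receptors, Acvr2b held 66.5% ± 6.44 in ES cells against 15.2% ± 0.61 in NMuMG and 10.8% ± 2.46 in NIH3T3. Bmpr2 held 49.0% ± 2.58 in NMuMG, 69.4% ± 1.63 in NIH3T3 and 12.6% ± 3.17 in ES cells, and Acvr2a held 35.9% ± 3.03, 19.8% ± 3.59 and 20.9% ± 6.63 in the same order. Exact permutation tests (two-sided) over 21 pairwise comparisons gave, where replicates did not overlap, p = 0.0571 for 3 against 4 replicates (adjusted p = 0.12) and p = 0.1 for 3 against 3 (adjusted p = 0.131), the smallest values these designs allow, so no share could pass. Replicates of NIH3T3 and NMuMG overlapped for all 4 type I receptors, with exact permutation p = 0.4 for Acvr1, 0.571 for Bmpr1a, 0.343 for Acvrl1 and 1 for Bmpr1b, and those of ES cells and NIH3T3 for Acvr2a (p = 0.9).

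The fourth comparison asks whether NMuMG cells with the reporter differ from their parent. Serpinh1, a collagen chaperone (chromosome 7, 99345375 to 99353239), stood at 61.1 and 56.4 FPKM in the parental replicates and at 0.34 and 0.40 in the reporter replicates, a log2 change of -5.45 (SE 0.194, n = 2 each, limma adjusted p = 0.00295). Axl, a receptor tyrosine kinase (chromosome 7, 25756500 to 25788733), fell from 28.0 and 27.4 to 0.49 and 0.41 FPKM (-4.31, SE 0.167, adjusted p = 0.00295). The imprinted zinc-finger gene Peg3 fell by 4.27 (SE 0.217), as did the lipid flippase Atp11a (-3.55, SE 0.31) and the surface protein Tm4sf1 (-3.42, SE 0.172). The small nucleolar RNA Snora34 was listed at 0 in both parental replicates and at 47.2 and 46.8 FPKM in the reporter replicates. A630095E13Rik, a gene without a described function, rose by 2.33 (SE 0.238, adjusted p = 0.047). 1110001A16Rik, Ccl27a and Pcdhgb5 were called higher as well, but each was listed at 0 in the parental replicates with an upper bound above 0, and each overlaps another table entry. In all 26 of 12276 genes were called, 6 higher and 20 lower in the reporter cultures, with 635 at an unadjusted p under 0.05. With the library series as a term 8 genes were called. Without NMuMG replicate 2 or without NMuMG replicate 4 the count was 0 (limma), with Serpinh1 still at -5.42 and -5.48, without NMuMG replicate 1 it was 62, and without ES replicate 2 or 4 it was 15 or 16.

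**Figure D3:**
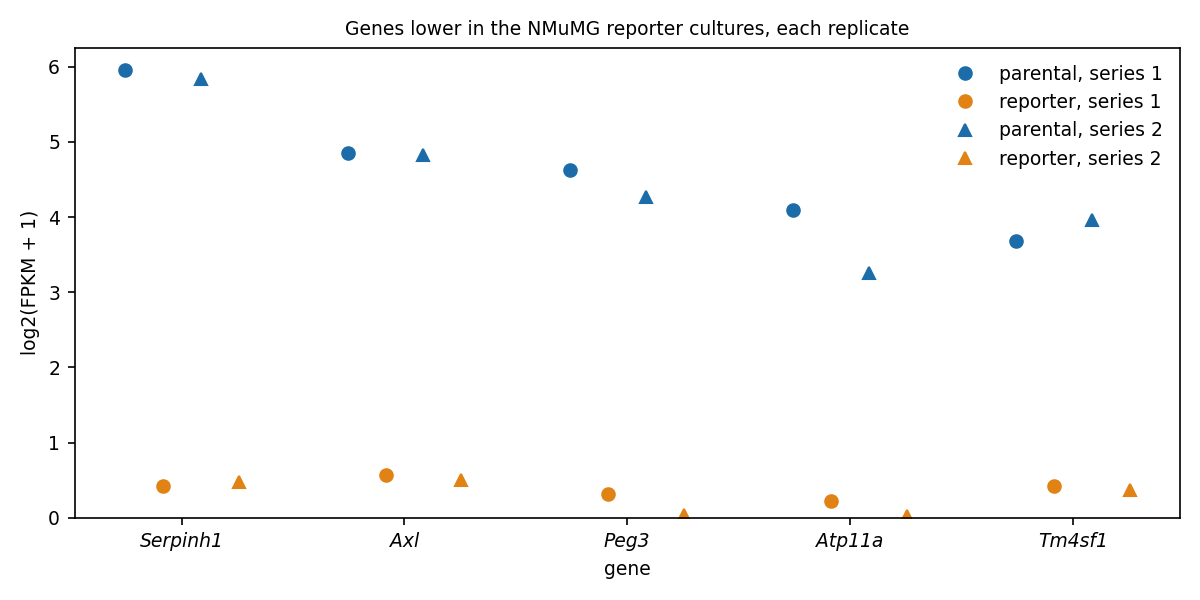
Log2(FPKM + 1) of the 5 genes with the largest decrease in NMuMG reporter cultures, for each of 4 replicates, with parental and reporter replicates in different colours and the library series in different symbols. Serpinh1 was at 61.1 and 56.4 FPKM in the parental and 0.34 and 0.40 FPKM in the reporter replicates.

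No BMP receptor was called between reporter and parental NMuMG cells: the log2 changes were 0.27 for Acvr1, -0.28 for Bmpr1a, 0.17 for Bmpr2, 0.10 for Acvr2a and 0.13 for Acvr2b. No member of the BMP target list was called either, and that list gave camera adjusted p = 0.377. The proliferation list was lower as a whole (median log2 change -1.504, camera adjusted p = 9.76e-05, and adjusted p = 0.874 with an estimated correlation), as was the interferon-stimulated list (median -2.18, adjusted p = 0.000315, and adjusted p = 0.874 with an estimated correlation), with 0 of 20 and 0 of 10 members called over all genes or adjusted over the list alone (limma). The first follows reporter replicate 4, where Plk1 stood at 1.46 FPKM against 10.2 and 52.6 in the parental replicates and 19.3 in reporter replicate 2. The mean log2 level of that list was 4.15 and 5.62 in parental replicates 1 and 3 and 4.55 and 2.66 in reporter replicates 2 and 4. It was thus lower in the reporter culture in library series 2 and not in series 1. The second follows parental replicate 3, where the ubiquitin-like Isg15 stood at 258 FPKM against 1.55, 0.59 and 0.71 in replicates 1, 2 and 4.

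The fifth comparison asks the same of ES cells, with 1 parental replicate that is assumed to vary like the other groups. Fits without an ES replicate hold 1 parental and 1 reporter ES culture, so their spread comes from NMuMG alone and their counts say little. Without ES replicate 2 the reporter culture is also of another library series than the parental one. Zscan4d, a gene of the early embryo expressed in a small part of ES cells, stood at 28.0 FPKM in the parental replicate and at 0.39 and 0.27 in the runs of reporter replicate 2 and 1.09 in reporter replicate 4 (log2 change -4.12, SE 0.327, limma adjusted p = 0.033). Its relatives Zscan4e (-4.10, SE 0.349) and Zscan4b (-4.04, SE 0.301) fell as well. The kinase gene Pim2, a target of LIF signalling, fell from 80.4 FPKM to 6.13, 6.56 and 5.99 (-3.51, SE 0.261), and the stress gene Gadd45g fell by 3.48 (SE 0.247). In all 12 of 12276 genes were called, 0 higher and 12 lower in the reporter cultures (limma), with 1099 at an unadjusted p under 0.05. The 3 with the smallest p among the higher genes did not pass: Cpe (2.29, adjusted p = 0.0543), Triml1 (2.13, adjusted p = 0.0566) and Mroh1, listed at 0 in the parental replicate. With the series as a term 0 genes were called, with 1111 at an unadjusted p under 0.05. The count was 0 without NMuMG replicate 2 or 4, 1 without NMuMG replicate 1 or 3, 198 without ES replicate 2 (68 higher and 130 lower) and 185 without ES replicate 4 (71 and 114). Higher genes were also called with a pseudocount of 0.1 (7 higher and 6 lower, 3 of the 13 shared) and with no filter (47 and 178). None of the 12 genes kept its call when any NMuMG replicate was left out. No BMP receptor was called. The Notch list (median log2 change -0.58, camera adjusted p = 0.0125) and the epithelial list (-0.22, adjusted p = 0.0267) were lower as a whole, and adjusted p = 0.886 with an estimated correlation for both, with no member called over all genes and 3 and 4 members adjusted over the list alone. Adjusted over the list alone 8 of 25 pluripotency genes were called as well (camera adjusted p = 0.0952), and 2 of 11 BMP targets and 2 of 14 ligands.

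The sixth comparison tests whether the reporter effects differ between ES and NMuMG cells. Fits without an ES replicate have the same limit as in the fifth comparison. It called 3 genes of 12276: Serpinh1 (difference of log2 changes 4.64, SE 0.306), Axl (4.24, SE 0.264) and 1110001A16Rik, each with limma adjusted p = 0.0486, and 968 were at an unadjusted p under 0.05. Serpinh1 changed by -0.81 (adjusted p = 0.388) between ES reporter and parental cultures, and Axl was at most 0.375 FPKM in any ES library. 1110001A16Rik was listed at 0 in every ES library and, with an upper bound above 0, in the parental NMuMG replicates, so no difference is given for it. A series term left 0 genes called, with 1018 at an unadjusted p under 0.05, and all 3 lost their call without any 1 of the 4 NMuMG replicates, although the difference for Serpinh1 stayed at 4.58 to 4.69 there and at 4.58 with the term. The count was 5 without NMuMG replicate 1, 0 without NMuMG replicate 2, 3 or 4, 194 without ES replicate 2 and 198 without ES replicate 4. Camera called the epithelial (adjusted p = 0.0155), Notch (0.0275), proliferation (0.0272) and interferon-stimulated (0.0458) lists, each with adjusted p = 0.856 with an estimated correlation, and with no member called over all genes. In ES replicates 1, 2 and 4 the means (log2) were 6.12, 6.25 and 6.13 for proliferation and 1.6, 1.63 and 1.44 for interferon-stimulated genes. The proliferation and interferon-stimulated calls thus mostly restate the NMuMG changes, which follow NMuMG reporter replicate 4 and parental replicate 3. Adjusted over the list alone 2 epithelial members and 1 Notch member were called, and 5 pluripotency, 1 ligand, 1 Eph and ephrin and 1 hedgehog member.

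Replicates differed more than repeated runs of 1 culture and far less than lines. The SD of log2 differences over genes was 0.245 between the 2 technical runs of an ES reporter culture (r = 0.993 across genes, which are not independent replicates). Its median over pairs of replicates was 0.659 in ES cells, 0.645 in NIH3T3 and 0.698 in NMuMG, and 1.78 between libraries of different lines. The first principal component held 50% of the variance and set ES cells apart from the other lines, and the second held 36.3% and set NMuMG apart from NIH3T3.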

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

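The counts over other splits of the samples were chosen before the data were examined, and the splits kept within library series and the tests on the interferon-stimulated genes and on the genes that differ in the NMuMG reporter cultures were chosen only after the result was seen.

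Other splits of the replicates called fewer genes than the real grouping. Of 35 splits of the 7 replicates of ES and NMuMG, 1, the real one, gave 5651 genes, and the highest other gave 4007. Of 35 splits of NIH3T3 and NMuMG, 1, again the real one, gave 3085, and the highest other gave 447. These splits exchange replicates between library series. The series differed within NMuMG, where series 2 against 1 called 21 genes (limma), so these splits cannot exclude chance. Kept within library series there are 18 and 3 splits, too few for a share under 0.05, and the highest other gave 4007 and 1. The 6 replicates of ES and NIH3T3 make 10 splits, too few for a share under 0.05: the real split gave 5315 and was the 1 with as many genes, and the highest other gave 1.

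A single NMuMG replicate lay far from the others for 8 of 111 named genes and 4 of 27 list means, where its gap to the nearest other replicate, as a share of the whole range, passed Dixon's 95% critical value. Chance does so for about 1 in 20 groups. The smooth muscle actin Acta2 was at 1.99 FPKM in replicate 1 and at most 0.11 in the others (ratio 0.953). The cyclin Ccnd3 was at 38.5 FPKM in replicate 3 and 31.0, 31.5 and 31.4 in replicates 1, 2 and 4 (0.935). The cyclin-dependent kinase inhibitor Cdkn2c was at 4.30 FPKM in replicate 4 and 11.7 to 13.7 in the others (0.857), and the muscle filament Des was at 1.27 FPKM in replicate 4 and at most 0.24 in the others (0.855). The Wnt co-receptor Lrp5 was at 59.4 FPKM in replicate 4 and 38.0 to 39.7 in the others (0.902), and Runx2 was at 7.02 FPKM in replicate 4 and 8.66 to 8.74 in the others (0.962). Tmem176b was at 877 FPKM in replicate 1 and 612 to 631 in the others (0.916). Isg15 gave a ratio of 0.907. The list means gave 0.847 for the basal mammary genes, 0.845 for the hedgehog genes, 0.84 for the p53 and INK4 genes and 0.889 for the interferon-stimulated genes. The ratio is taken against the range, so a small gap can pass. The hedgehog means were 1.6, 1.6, 1.59 and 1.54 (log2) in replicates 1 to 4, and the p53 and INK4 means 4.94, 5.21, 5.17 and 5.2. The basal mammary mean was 3.06 in replicate 4 and 2.58 to 2.66 in the others.

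An interaction test of the reporter effects in ES and NMuMG cells called 3 genes: Serpinh1 at 4.64, Axl at 4.24 and 1110001A16Rik at -3.40 on the log2 scale. Axl was at most 0.375 FPKM in ES cells and 1110001A16Rik was listed at 0 there, so for these 2 the value restates the NMuMG change. The value for 1110001A16Rik measures no size: the gene was also listed at 0 in the parental NMuMG replicates with an upper bound above 0, the value was -4.33 and -6.60 with pseudocounts of 0.5 and 0.1, and the gene drops out where uncertain zeros are left out. For Serpinh1 the value stayed at 4.58 to 4.69 without any 1 of the 4 NMuMG replicates and at 4.58 with the replicate number as a block, although it was not called there, and with the block 0 genes were called (limma, 1018 at an unadjusted p under 0.05).

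Interferon-stimulated genes were high in 2 libraries, parental NMuMG replicate 3 and parental NIH3T3 replicate 1. The mean log2 level of the list was 6.33 in the first, against 2.24, 1.99 and 1.73 in the other NMuMG replicates, and 5.35 in the second, against 2.09 and 2.55. Isg15 reached 258 and 164 FPKM in them, and the antiviral membrane protein Bst2 834 and 771. An effect shared by the whole of library series 2 is unlikely, since the larger of the differences of NMuMG replicate 4 and ES replicate 4 from series 1 was -0.17, and parental status of the culture alone is unlikely too, since the larger parental minus reporter difference in series 1 was 0.25. White blood cells carrying the transcripts are unlikely, with Ptprc, Coro1a, Lyz2, Itgam and Cd3e at 0.31 FPKM or less in both libraries; the haemoglobin Hba-a1, set aside as a red cell gene after its value was seen, was at 1.5 FPKM in NIH3T3 replicate 1. What stays open, untested, is exposure of both cultures to interferon or a virus, or a handling step they shared, as they are the only parental libraries of series 2.

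The 20 genes lower and 6 higher in NMuMG reporter cultures were weighed against 3 technical explanations. Fibroblasts carried in the parental cultures are unlikely. Of the lower genes, 11 averaged at least 10 FPKM in NIH3T3 and would need a median of 13.5% of the NIH3T3 level. For 17 fibroblast genes of at least 100 FPKM in NIH3T3, the parental minus reporter difference was a median of 0.01% of that level (highest 2.61%). Loss of a chromosome segment of 1 Mb or more around each gene is unlikely as the shared cause, since 439 tested neighbours had a median log2 change of -0.002 and 3.0% of them were at least 2-fold lower. Reads divided between overlapping entries could explain 5 of the 6 higher genes, as 5 overlap another entry (Fisher's exact test against the 17.6% of other tested genes, p = 0.000865), but only 6 of the 20 lower genes do (p = 0.146, exact), which leaves 14, Serpinh1, Axl and Tm4sf1 among them. A difference between clones and an effect of the reporter stay open and untested, since the design confounds them.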

How the results depend on the processing

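The 3 line comparisons kept most of their calls. Their counts stayed within 1.5-fold under other pseudocounts, filters, scalings, technical runs, the series as a term and array weights, and with each replicate left out (5490 to 5833 for ES against NMuMG, 2909 to 3345 for NIH3T3 against NMuMG and 3382 without both interferon-high libraries, 4941 to 5461 for ES against NIH3T3). They dropped in the fits with an arm of 1 library: to 2412, 941 and 2041 in parental cultures only, and to 2135, 907 and 1735 within library series 2. ES against NMuMG within series 1, with 2 replicates each, gave 5865. Without a fold minimum NIH3T3 against NMuMG gave 4993. Fits within series were chosen after seeing the data.

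The reporter comparisons moved with many choices, and the cause was not tested. Fits without an ES replicate take their spread from NMuMG alone, so their counts say little. None of the 12 genes called in ES cells kept its call when any NMuMG replicate was left out. In NMuMG the count of 26 became 59 and 40 with pseudocounts of 0.1 and 0.5, 17 with no filter, 16 with a filter at 5 FPKM, 56 with TPM, 10 with quantile scaling, 8 with the replicate number as a block, and 0 to 62 with each replicate left out (0 without NMuMG replicate 2 or 4, 62 without NMuMG replicate 1). In ES cells the count of 12 became 1 with a pseudocount of 0.5, 225 with no filter, 3 with a filter at 5 FPKM, 0 with quantile scaling and 0 with the replicate block (limma, 1111 at an unadjusted p under 0.05), 19 with Mir and Snor genes left out, and 0 to 198 with each replicate left out (0 without NMuMG replicate 2 or 4, 198 without ES replicate 2, 185 without ES replicate 4, 1 without NMuMG replicate 1 or 3). The difference of the reporter effects went from 3 to 22 and 7 with the pseudocounts, 176 with no filter, 5 with a filter at 5 FPKM, 7 with median-of-ratios scaling, 0 with quantile scaling, 6 with technical run 1 alone, 6 with symbols on 1 entry only, 6 without LOWDATA entries, 6 without Mir and Snor genes, 0 with the replicate block (1018 at an unadjusted p under 0.05), and 0 to 198 with each replicate left out (0 without NMuMG replicate 2, 3 or 4, 198 without ES replicate 4). The change between replicate numbers correlated across genes at r = 0.274 between NMuMG parental and NMuMG reporter cultures. With ES reporter cultures it was no lower, at 0.339 for NMuMG parental and 0.366 for NMuMG reporter cultures. The correlation therefore does not show a pairing of cultures within a line. Replicate numbers are also the library series here, and the main reporter fits hold no series term.

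Lists called by camera numbered 4, 10 and 5 in the line comparisons, and 1, 0 and 1 with an estimated correlation and 17, 19 and 20 with fry, which asks whether a list moves one way and not whether it moves more than other genes. In the reporter comparisons they numbered 2, 2 and 4, and 0, 0 and 0 with an estimated correlation and with fry, and with a pseudocount of 0.1 they were 1 in ES cells and 0 for the difference of the effects. The cause was not tested.

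The share of Acvr2b in ES cells was 66.5% over all cultures and 73.6% in the parental culture only. The log2 change of Acvr1 in NIH3T3 versus NMuMG, -0.09 and not called, turned to 0.013 with quantile scaling and 0.016 in parental cultures only, and ran from -0.19 to 0.014 with each replicate left out (0.014 without NMuMG replicate 4 and 0.002 without NIH3T3 replicate 2). Fgfr2 in ES versus NIH3T3 turned to 0.069 in parental cultures only. The cause was not tested. Quantile scaling moved the median of all genes by 0.162 and no filter moved it by 0.103 in ES against NMuMG. TPM moved it by 0.157 for the difference of reporter effects.

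For named genes, 2767 of 2839 values under an alternative kept their call in ES against NMuMG, 2233 of 2363 in NIH3T3 against NMuMG, 2498 of 2597 in ES against NIH3T3, 167 of 214 in the NMuMG reporter comparison, 104 of 164 in the ES reporter comparison and 42 of 62 for the difference. Depth is known only relative to other libraries, so its limit on low values could not be computed. On simulated data with independent noise the ES reporter comparison recovered 30 of 100 genes changed by 1.5 on the log2 scale, against 84 for ES against NMuMG.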

Other observations

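The list of genes of the state like the 2-cell embryo was written before their values were seen, and the test on its members outside the Zscan4 family and the tests on chromosomes were chosen only after the result was seen.

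The Zscan4 genes, which mark the embryo at the stage of 2 cells, were high in the parental ES culture. Zscan4c, a regulator of telomeres, was at 35.7 FPKM in parental replicate 1 and at 0.50 and 1.79 in reporter replicates 2 and 4, and Zscan4f was at 48.7 FPKM against 0.68 and 2.45. More cells in a state like the 2-cell embryo cannot be told apart from a change of this family alone. Of 13 other genes of that state, 3 reached 0.5 FPKM in an ES replicate, too few to decide, 2 of them under 2 FPKM in every ES replicate. These 3 of 3 were highest in the parental culture: the deubiquitinase gene Usp17la (1.82 FPKM against 0.06 and 0.22), Gm5662 (25.5 against 0.40 and 1.8) and the nuclear body gene Sp110 (1.09 against 0.02 and 0.15). They are not independent, and with 1 parental replicate the culture and the absence of the reporter cannot be separated.

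Whole chromosomes differed between reporter and parental NMuMG cultures. Over 340 genes of chromosome 15 the median log2 difference was 0.27 in series 1 and 0.28 in series 2, with 91.5% and 79.4% of genes above 0. Over 260 genes of chromosome 12 it was -0.25 and -0.31, over 390 genes of chromosome 10 it was 0.15 and 0.20, and over 237 genes of chromosome 14 it was -0.12 and -0.15. Every other chromosome lay within 0.09 of 0 in series 1 and within 0.10 in series 2. A different number of chromosome copies in some or all cells may underlie this: in series 2, 8 of 8 parts (a left and a right part of each chromosome) moved as in series 1, though 3 copies in place of 2 would give 0.58 if every cell had them. A difference between libraries in how chromosomes are sampled is unlikely, since the median farthest from 0 between the series of the same culture was 0.07. Whether the copies differ was not measured.

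In ES cells chromosome 8 was higher in both reporter replicates than in the parental culture, with median log2 differences of 0.33 and 0.29 over 414 genes and 81.6% and 80.0% of them above 0. Every other chromosome lay within 0.09 of 0. Both differences share the 1 parental replicate, and no explanation was tested.

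The NMuMG culture with the lowest proliferation genes, reporter replicate 4, had Cdkn2b at 129 FPKM (41.3, 58.5 and 57.0 in replicates 1, 2 and 3), Ccnd1 at 719 (183, 384 and 414) and Cdkn1a at 370 (172, 282 and 216). The p53 and INK4 list as a whole was not raised there, with a mean log2 level of 5.20 (4.94, 5.21 and 5.17 in replicates 1, 2 and 3). Its member Cdkn2c was lowest in replicate 4. In the 4 NMuMG replicates alone (10916 genes tested with limma), reporter against parental called 7 genes (488 at an unadjusted p under 0.05), library series 2 against 1 called 21 (1077), and the crossed split called 0 (213).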
